A study of Equus caballus with 10 samples.

How the data were processed

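Sperm RNA of 10 warmblood stallions (Equus caballus) was measured on 10 Affymetrix expression arrays, 1 per stallion. Per the labels' protocols, 4 ejaculates were sampled per stallion at an insemination centre, RNA was extracted with TRI Reagent, treated with DNase and cleaned on columns, and biotin-labelled cRNA was hybridised. Whether the 4 ejaculates of a stallion were pooled is not given in the sources used here. The season and fertility class of each array came from the sample characteristics: 2 stallions in autumn with high fertility (stallions 1 and 2), 3 in spring with high fertility (3, 4 and 9), 2 in autumn with low fertility (5 and 6) and 3 in spring with low fertility (7, 8 and 10). The title of stallion 9's array begins with the letters of the autumn titles while its season field says spring. It was kept in spring, and the tests of probe sets and gene lists were computed again with it in autumn. The later tests on splits of the arrays and on explanations were run only with it in spring. The labels also place the sampling of every stallion, those labelled autumn included, in the breeding season. How fertility was measured is not given in the sources used here. Each array is a different stallion, so the spread between arrays of a group is a spread between animals and handling together.

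The values used are log2 signals per probe set as deposited by the authors, with 2 decimals. The submitters' processing notes name GCOS 1.1.1 and Affymetrix Expression Console 1.1 without saying what each did. The summarisation, background and scaling steps are not given in the sources used here. No value lies below 4, and between 842 and 2920 of the 30559 probe sets per array sit exactly on that floor, so differences of probe sets near it are understated. Array medians ran from 5.07 to 5.49, so the deposited values had not been made equal by quantile normalization. The values were tested as deposited. Signal over background could not be assessed beyond the floor, and the number of arrays limits the precision.

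Probe sets were named from a table of the platform's annotation: 16789 had 1 gene symbol, 343 had several and 13427 were unnamed there, and symbols can be old. No probe set with several symbols was named. Control probe sets could not be told from others in the sources used here, so all 30559 were tested, where the plan had been to leave controls out.

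Season, fertility class and their interaction were tested with limma 3.58.1 in R 4.3.3. One linear model with a mean for each of the 4 groups was fitted to all 10 arrays, so that the groups shared an estimate of the spread (6 residual and 2.96 prior degrees of freedom). The season difference is spring minus autumn averaged over the fertility classes, the fertility difference is low minus high averaged over the seasons, and the interaction is the spring minus autumn difference in low-fertility stallions minus that in high-fertility stallions. Tests were two-sided with eBayes moderation, and a Benjamini-Hochberg adjusted p under 0.05 over all probe sets was the threshold. The series describes a 2-way layout by season and fertility. The fit without moderation, which is closest to it, was an alternative.

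The rule for naming genes was fixed before the data were examined. For season and fertility it took single-symbol probe sets past the threshold with the same sign within both classes of the other factor, up to 12 per direction. Each direction was filled up to 6 with those of smallest unadjusted p. As applied, the fill also took only probe sets with the same sign within both classes of the other factor. For the interaction it took up to 6 per direction, filled up to 3. It also took up to 4 members with the smallest unadjusted p of each gene list and the 15 named probe sets with the highest mean. Genes named outside this rule are said to have been chosen after their values were seen. The 26 gene lists, 870 genes in all, were also fixed beforehand and cover sperm structures, late spermatid and earlier germ cells, other cell types of semen and the male tract, general cell functions, clock and hormone genes, and stallion fertility candidates. Of these genes 709 were measured. The 25 lists with at least 5 measured genes were tested with limma's camera, using the probe set with the highest mean per gene and a preset correlation of 0.01. The alternatives were a correlation estimated from the data and fry. The list of mitochondrially encoded transcripts had 1 measured gene and was not tested.

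The fits were tested on simulated arrays with the real means and spreads, 30559 probe sets and 50 changed ones per size. The changed ones were drawn only from probe sets with means above every array median, so the shares do not cover weaker ones. For season, 30% of changes of 1 log2 unit, 72% of 2, 82% of 3 and 100% of 4 were recovered, with 8 false calls. For fertility the shares were 20%, 76%, 78% and 94%, with 9 false calls. For the interaction they were 0%, 10%, 52% and 60%, with 1 false call. A translation factor list shifted by 0.5 was called for season and for fertility but not for the interaction. Genes varied independently in the simulation, so it cannot show how the preset correlation behaves where list members vary together.

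Alternatives fixed beforehand were quantile normalization, median centring, a filter that kept the probe sets with a mean above the median, list values averaged over a gene's probe sets, a model without the interaction, a single factor, no moderation, eBayes with trend and robust options, array weights, stallion 9 in autumn, an additional 1.5-fold minimum, and each array left out. Alternatives chosen after seeing the data were leaving out the arrays of stallions 2, 9 and 10, the array median as a covariate, single-symbol probe sets alone, and a term for the 2 arrays (stallions 9 and 10) whose titles carry no running number. No batch or scan date is given in the sources used here.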

Results

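Transcript abundance was measured in ejaculated spermatozoa of 10 warmblood stallions, 1 array each, in a layout by season and fertility class: autumn with high fertility (n = 2), spring with high fertility (n = 3), autumn with low fertility (n = 2) and spring with low fertility (n = 3). All values are deposited log2 signals with a floor of 4. No 2 arrays held identical values. Pairs of arrays within a group correlated across probe sets with r between 0.791 and 0.907 (median 0.858, 8 pairs), and pairs from different groups with r between 0.794 and 0.918 (median 0.873, 37 pairs), so the median correlation was not higher within groups.

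Probe sets differ in how strongly they bind their targets, so signals of different genes do not rank their abundance. Among the 15 named probe sets with the highest mean signal was that of PRM1, a protamine that packs sperm DNA, at 12.79 ± 0.66 (SD, n = 10). Those of the transition proteins that precede protamines on sperm DNA were also among them, TNP2 at 11.92 ± 1.11 and TNP1 at 11.49 ± 1.16, with HMGB4 at 11.49 ± 0.84. The 15 also held genes of the outer dense fibres of the tail, ODF2 at 11.10 ± 0.49 and ODF1 at 11.03 ± 0.81, and the sperm protein genes SPA17 at 10.29 ± 0.97 and CRISP2 at 10.22 ± 0.87 and the spermiogenesis kinase gene TSSK6 at 10.10 ± 0.59. The others were LOC100070085 at 11.69, ATF2 at 10.78, AKAP12 at 10.44, LELP1 at 10.26, PPDPF at 10.15 and ZNF408 at 10.11. The sperm chromatin list averaged 9.12 over its 12 measured genes and the late spermatid list 7.60 over 33. The mean signals of the lists of other cell types, given as levels of their own probe sets and not as shares of cells, were as follows: germ cell meiosis averaged 5.69, spermatogonia 5.84, Sertoli and Leydig cells 5.44, epididymis and accessory gland epithelium 5.46, general epithelium 5.51, leukocytes 5.43, erythroid cells 5.76, and stromal and endothelial cells 5.38. ND1, the only measured member of the mitochondrially encoded list, stood at 10.05.

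On the arrays of stallions 2, 9 and 10, the 3 with the lowest medians (at most 5.10, against at least 5.24 on the others) and the most probe sets at the floor (2764 or more, against 2129 or fewer), the sperm chromatin list averaged 8.25 to 8.40, against 9.25 to 9.73 on the other 7. TNP2 stood at 10.03 to 10.62 on these 3 arrays and at 11.99 or more on the others. The ribosomal protein list averaged 6.24 to 6.51 on them and 7.01 to 7.47 on the others. The germ cell meiosis list (5.23 to 5.38 against 5.61 to 5.99), the Sertoli and Leydig cell list (5.15 to 5.29 against 5.40 to 5.76), the erythroid list (5.30 to 5.54 against 5.69 to 5.99), the oxidative phosphorylation list (5.67 to 5.80 against 6.09 to 6.30) and the proteasome and ubiquitin list (5.57 to 5.67 against 5.98 to 6.14) also lay lower on them. The spermatogonia list reached from 5.49 to 5.82 on them and from 5.82 to 6.04 on the others. The leukocyte list overlapped, at 5.28 to 5.38 against 5.30 to 5.75, as did those of general epithelium, epididymis and accessory glands, and stromal and endothelial cells. These arrays belong to 3 different groups, and the autumn low-fertility group holds none of them. The first principal component, with 34.7% of the variance, placed the same 3 arrays at 50.9, 66.4 and 70.5 and the other 7 between -57.4 and 5.35.

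**Figure D1:**
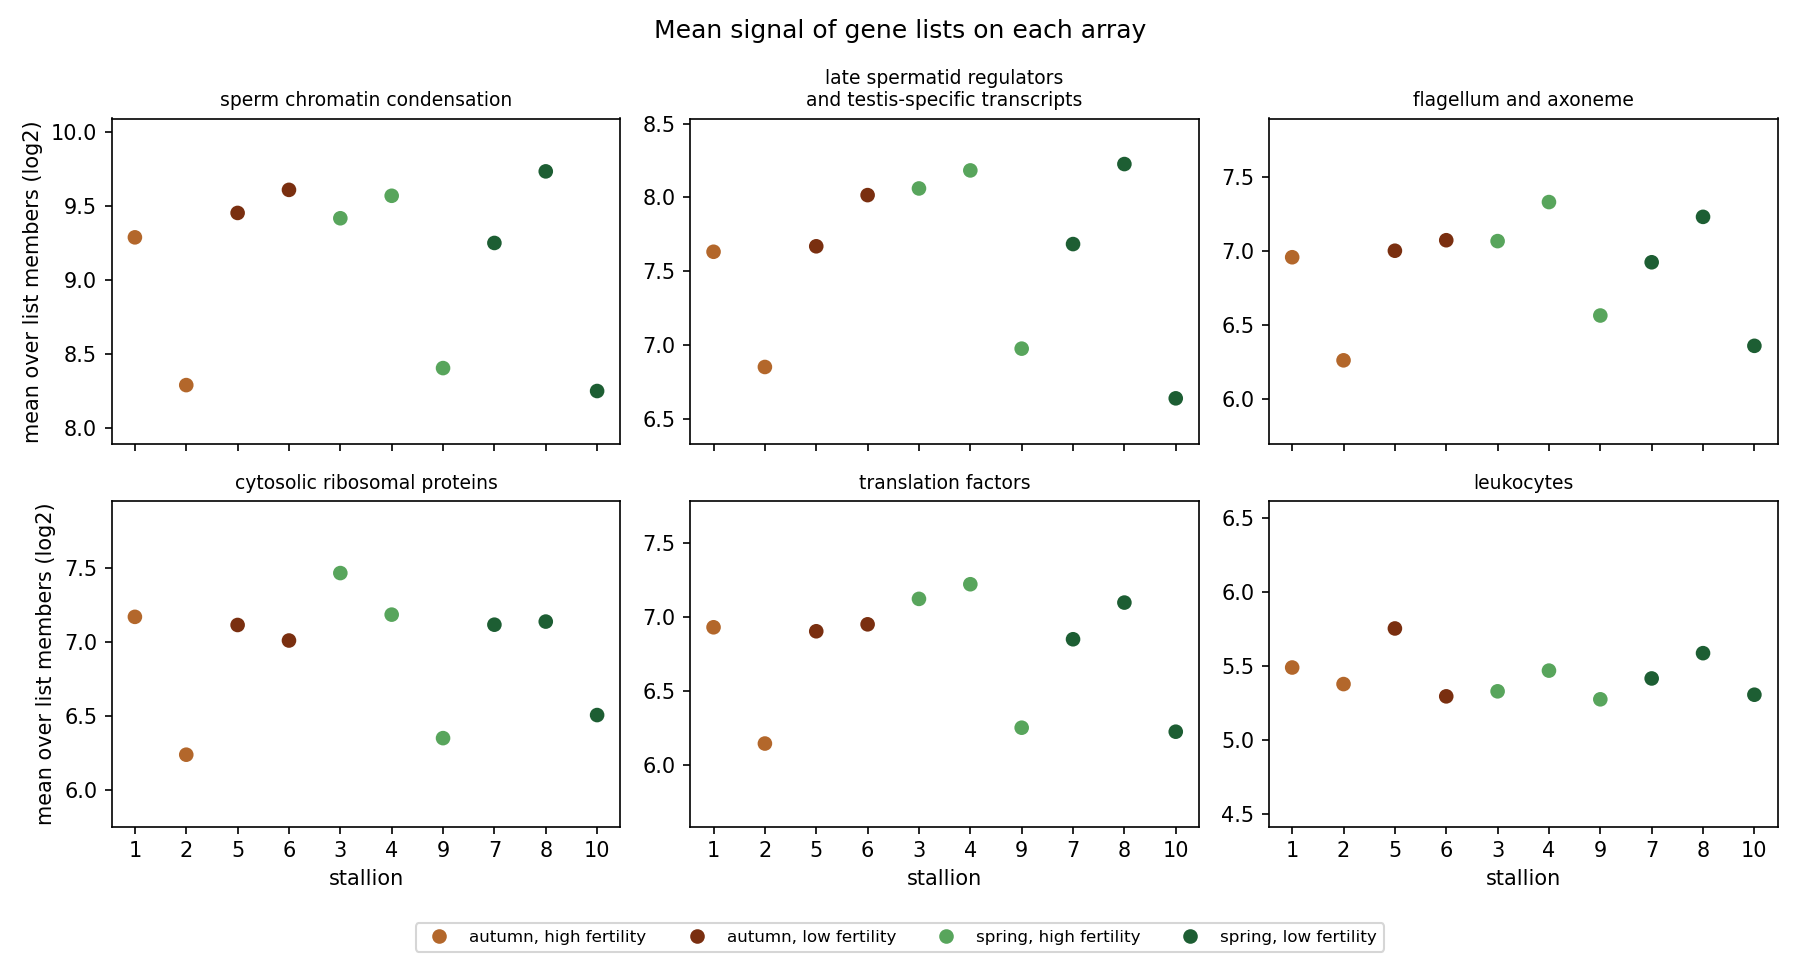
Mean deposited signal (log2, vertical axis) over the measured members of 6 gene lists on each array (horizontal axis, stallion number, colour by season and fertility class; each point is 1 array). The sperm chromatin list lies at 8.25 to 8.40 in stallions 2, 9 and 10 and at 9.25 to 9.73 in the other 7, while the leukocyte list shows no such gap.

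By season, 1 of 30559 probe sets passed the threshold in limma, that of LOC100061699, for which the annotation used here gives only this symbol, and which was lower in spring. Its difference was -2.89 (SE 0.19, adjusted p = 0.00288). The difference came from the low-fertility stallions: autumn averaged 11.09 ± 0.08 (SD, n = 2) and spring 5.80 ± 0.42 (n = 3), a difference of -5.29, against -0.50 in the high-fertility stallions, where autumn averaged 6.17 ± 0.02 (n = 2) and spring 5.66 ± 0.22 (n = 3). The next smallest adjusted p was 0.18. Unadjusted p under 0.05 was reached by 1278 probe sets, 308 higher and 970 lower in spring, where chance alone would give 1528. The median difference over all probe sets was itself -0.0475 and array medians were not equal, so this imbalance need not reflect season alone. The call was lost in the models without the interaction term or with season alone (adjusted p = 1 in both), without stallion 2 (adjusted p = 0.0501), without stallion 5 (adjusted p = 0.061) and without the arrays of stallions 2, 9 and 10 (adjusted p = 0.991), and over all alternatives its adjusted p ran from 0.000711 to 1.

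The genes named next for season had the smallest unadjusted p among those with the same sign of difference in both fertility classes. None passed the threshold (all adjusted p = 1). With the higher mean in spring were GALP, which encodes the galanin-like peptide, at 1.01 (SE 0.21), and PPM1G, a protein phosphatase gene, at 0.78 (SE 0.17). So were METAP1D at 0.77 (SE 0.19), the ubiquitin-conjugating enzyme gene UBE2E3 at 0.70 (SE 0.19), and LOC100068295 and LOC100064229 at 0.68 and 1.16. With the lower mean in spring were PPP1R14C, a phosphatase inhibitor gene, at -1.07 (SE 0.19), PVRIG at -0.86 (SE 0.16), CSKMT at -0.71 (SE 0.13), CYP39A1, an oxysterol hydroxylase gene, at -1.20 (SE 0.23), and RILPL1 at -1.64 (SE 0.34). The same sign did not mean the same size in both classes. From autumn to spring, GALP went from 5.735 to 7.49 in high and from 7.165 to 7.42 in low fertility. CYP39A1 went from 5.395 to 5.25 in high and from 7.315 to 5.07 in low fertility. LOC100064229 was more alike, from 6.38 to 7.46 in high and from 6.215 to 7.47 in low fertility.

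Of 25 gene lists, 1 passed for season, against 7 with stallion 9 in autumn, 8 without stallions 2, 9 and 10 and 10 with a term for the title format. The 64 measured cytosolic ribosomal protein genes had a mean difference of 0.08, 38 higher and 26 lower in spring (camera adjusted p = 0.0386, and adjusted p = 0.97 with an estimated correlation). The list mean was higher in spring by 0.30 in high-fertility stallions and lower by -0.14 in low-fertility stallions. Its members with the smallest p included RPS28 at 0.56 and RPS27A at 0.49, and neither passed. The mean was -0.16 without stallion 2 and -0.04 without stallion 3, both with the call lost, as it also was without stallion 5 (adjusted p = 0.771), without stallion 7 (adjusted p = 0.175), after quantile normalization (adjusted p = 0.0791) and with the filter on low means (adjusted p = 0.0572), and over all alternatives its adjusted p ran from 2.06e-07 to 0.97 and its mean from -0.16 to 0.34. The other 24 lists had adjusted p between 0.103 and 0.948. Among them the circadian clock list averaged -0.02 over 21 genes, with CIART at 0.34 and CRY1 at -0.30. The hormone receptor and photoperiod list averaged -0.07 over 26, with 13 higher and 13 lower in spring. Its members with the smallest p were the deiodinase genes DIO2 at -0.47 and DIO3 at -0.67, the oestrogen receptor gene ESR2 at -0.36 and, in the other direction, IGF1R at 0.44. The heat shock list averaged 0.03, with the mitochondrial chaperone genes HSPD1 at -0.86 and HSPA9 at -0.33. The acrosome list averaged 0.06, the sperm ion channel list 0.06, the antioxidant list 0.02, the oxidative phosphorylation list 0.03, the stromal and endothelial list -0.04 and the erythroid list 0.06. In 5 of the 25 lists camera's direction, which is relative to all other genes, differed in sign from the mean, and in 2 the mean and median differed in sign.

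By fertility class, LOC100061699 was again the only 1 of 30559 probe sets past the threshold in limma, and it was higher in low-fertility stallions. Its difference was 2.53 (SE 0.19, adjusted p = 0.00911), made up of 4.93 in autumn and 0.14 in spring. The next smallest adjusted p was 0.554. Unadjusted p under 0.05 was reached by 790 probe sets, 555 higher and 235 lower in low fertility, where chance would give 1528. Over all probe sets the median difference was itself 0.05, so this imbalance need not reflect fertility class alone. The call was lost without stallion 1, 2, 4, 5 or 9, with adjusted p between 0.0592 and 0.163, without the arrays of stallions 2, 9 and 10 (adjusted p = 1), in the models without the interaction term or with fertility alone (adjusted p = 1 in both) and without moderation (adjusted p = 0.079). Over all alternatives its adjusted p ran from 0.0025 to 1.

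The genes named next for fertility had the smallest unadjusted p among those with the same sign of difference in both seasons, and none passed. PVRIG, which encodes a lymphocyte receptor, differed by 1.19 (SE 0.16, adjusted p = 0.554) and OLFM4 by 0.93 (SE 0.15, adjusted p = 0.683). CSTA, a cysteine protease inhibitor gene of epithelia, differed by 0.90 (SE 0.18), CLN8 by 0.67 (SE 0.14) and TSKS, a substrate of the testis-specific kinases, by 0.77 (SE 0.18). With the lower mean in low-fertility stallions were STYXL1 at -0.70 (SE 0.15), ZDHHC6 at -0.50 (SE 0.13), ZHX1 at -1.26 (SE 0.34), TFAP4 at -0.51 (SE 0.15), ISM2 at -0.53 (SE 0.16) and the olfactory receptor gene OR9Q2 at -0.48 (SE 0.15), all with adjusted p = 1. Here too the size could differ between the seasons. From high to low fertility, CLN8 went from 4.59 to 5.84 in autumn and from 5.39 to 5.47 in spring. OR9Q2 was more alike, from 5.1 to 4.685 in autumn and from 5.62 to 5.07 in spring.

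No gene list passed for fertility class in camera (3 of 25 at an unadjusted p under 0.05, 0 with an estimated correlation or fry). The sperm chromatin list had the smallest adjusted p, 0.203 (0.934 with an estimated correlation). All 12 of its measured members had the higher mean in low-fertility stallions, averaging 0.34, with BRDT, a reader of acetylated histones, at 0.64 (SE 0.22) and the testis histone gene H2BC1 at 0.70 (SE 0.29). Of the 3 arrays on which this list was low, those of stallions 2 and 9 are of high and that of stallion 10 of low fertility, and without them the list averaged 0.12 with 7 of 12 members higher (adjusted p = 0.5, and 0.992 with an estimated correlation). The spermatogonia list averaged -0.05 (adjusted p = 0.229) and the epididymis and accessory gland list -0.07 (adjusted p = 0.275), where BSP1, a seminal plasma protein gene, was at -1.14 (SE 0.59), with 8.40 and 7.19 in stallions 3 and 4 and 4.30 to 4.86 in the other 8. The stallion fertility candidates averaged 0.04 over 16 genes (adjusted p = 0.712), 9 higher and 7 lower, with FKBP6 at 0.41. CRISP3 was at -0.50 (SE 0.57), with 7.52 in stallion 3 and 4.25 to 5.17 in the other 9. The leukocyte list averaged 0.08, with S100A9 at 1.44 (SE 0.38) and S100A12 at 0.90 (SE 0.26) but FCER1G at -0.38 and TYROBP at -0.43. The general epithelium list averaged 0.05, sperm glycolysis 0.18, germ cell meiosis 0.13, Sertoli and Leydig cells 0.12, proteasome and ubiquitin 0.14, apoptosis 0.01, and inflammatory and interferon response 0.01. In 9 of the 25 lists camera's direction differed in sign from the mean, and in 2 the mean and median differed in sign.

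The interaction asks whether the season difference itself differed between fertility classes. LOC100061699 was the only 1 of 30559 probe sets past the threshold, at -4.78 (SE 0.38, adjusted p = 0.0148). It stood at 11.14 and 11.03 in the autumn low-fertility stallions and at 5.43 to 6.26 in the other 8. Among single-symbol probe sets with a negative interaction, the next smallest p, not past the threshold, was that of GM2A, the ganglioside activator gene, at -2.88 (SE 0.42, adjusted p = 0.564), with 8.63 and 8.50 in the same stallions and 5.32 to 6.41 in the others. FHIP1A was at -1.63 (SE 0.34). In the other direction, PLXNA4, a semaphorin co-receptor gene, was at 1.32 (SE 0.25), PHRF1 at 1.87 (SE 0.36) and DBN1, an actin-binding protein gene, at 1.94 (SE 0.44), all with adjusted p = 1. With stallion 9 in autumn, PLXNA4 was at 1.04, PHRF1 at 1.335 and DBN1 at 1.20. Unadjusted p under 0.05 was reached by 1158 probe sets, 455 positive and 703 negative, where chance would give 1528. Over all probe sets the median interaction was itself -0.07. The call for LOC100061699 was lost without stallion 1, 2, 3, 4, 5, 9 or 10, with adjusted p between 0.0683 and 0.247, without moderation (adjusted p = 0.148) and without the arrays of stallions 2, 9 and 10 (adjusted p = 1). Over all alternatives its adjusted p ran from 0.00425 to 1.

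**Figure D2:**
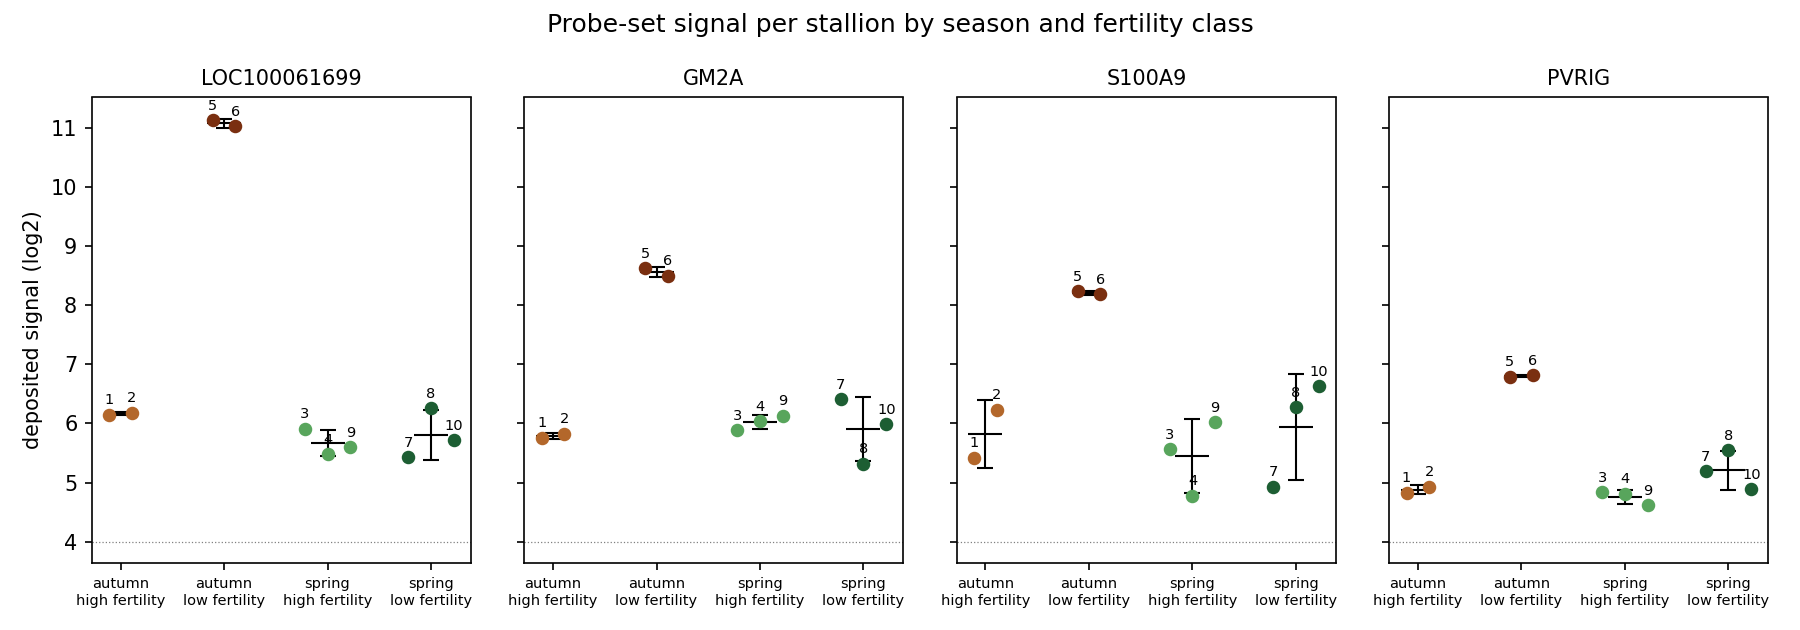
Deposited probe-set signal (log2, vertical axis; dotted line, floor of 4) of LOC100061699, GM2A, S100A9 and PVRIG by season and fertility class (horizontal axis). Points are stallions, numbered, and black bars are means with SD (n = 2 in autumn, n = 3 in spring); LOC100061699 is at 11.14 and 11.03 in stallions 5 and 6 and at 6.26 or below in the other 8, and the other 3 genes did not pass the threshold.

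Of 25 lists, 4 passed for the interaction in camera, all with negative means, and none with an estimated correlation (each adjusted p = 0.989) or with fry. The late spermatid list had the most negative mean, -0.82, with 33 of 33 measured genes negative (adjusted p = 0.0014). Its list mean was higher in spring by 0.50 in high-fertility stallions and lower by -0.33 in low-fertility stallions. CREM, the activator of postmeiotic genes, was at -2.08 (SE 0.86), SPATA3 at -2.29 (SE 0.94), SPATC1 at -1.86 (SE 0.78) and LELP1 at -1.35 (SE 0.59). The flagellum and axoneme list averaged -0.58 with 36 of 41 negative (adjusted p = 0.0134), including SPAG6, a protein of the axoneme's central pair, at -1.61 (SE 0.51) and the dynein heavy chain gene DNAH17 at -1.12 (SE 0.46). Translation factors averaged -0.53 with 29 of 33 negative (adjusted p = 0.0134), with EIF3L at -1.09 (SE 0.38), and cytosolic ribosomal proteins -0.44 with 56 of 64 negative (adjusted p = 0.0293), with RPS10 at -1.22 (SE 0.51). None of these genes passed on its own. The correlations estimated for the late spermatid, flagellum, translation factor and ribosomal lists were 0.55, 0.26, 0.385 and 0.50, against the preset 0.01. Members thus moved together, and the counts of negative members are not counts of independent genes. The median interaction over all probe sets was also negative, at -0.07. Over all lists and all 3 comparisons, 0 members passed, adjusted over all probe sets or adjusted over the list alone, by limma. An unadjusted p under 0.05 was found for 31 list entries for season, 18 for fertility and 25 for the interaction, each fewer than chance alone would give.

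Without stallion 2, which leaves 1 array in autumn with high fertility, translation factors averaged -0.14 and ribosomal proteins 0.03, the latter with the sign reversed. The arrays of stallions 2, 9 and 10, low in all 4 of the lists that passed, fall 1 each into the 3 groups other than autumn with low fertility. Without them 1 of the 4 lists passed, the late spermatid list (mean -0.38, adjusted p = 0.0291; 2.84e-06 to 0.989 over all its alternatives), with adjusted p = 0.959 with an estimated correlation. Of the 4 lists, 0 passed without stallion 6 or 10, 1 without stallion 2 or 4 and 2 without stallion 3. The remaining 21 lists had adjusted p between 0.0955 and 0.973, the smallest for the sperm chromatin list at -0.79. In 8 of the 25 lists camera's direction differed in sign from the mean.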

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

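The explanation tests for single patterns were all chosen after the results were seen, while the tests on other splits of the arrays were set before their outcome was known, apart from the count of splits that keep stallions 5 and 6 together. These results differed between groups by a test of the interaction: LOC100061699 at -4.78, and the list means of late spermatid transcripts at -0.82, flagellum and axoneme at -0.58, translation factors at -0.53 and ribosomal proteins at -0.44. The 4 lists did so only with camera's preset correlation: each had adjusted p = 0.989 with an estimated correlation and 0.87 with fry, and the interaction of each list's mean per array was less than 2 standard errors from 0.

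The signal of LOC100061699 in both autumn low-fertility stallions was at least 4.77 above that of any other stallion, while spring minus autumn was -0.50 in high-fertility stallions and low minus high fertility 0.14 in spring, so neither season alone nor fertility class alone gives these values. Scaling between the arrays as its cause is argued against by the size of this gap, since array medians ran only from 5.07 to 5.49. Quantile normalization could hardly have removed such a gap, and after it the limma interaction kept an adjusted p of 0.0166 (range over all its alternatives 0.00425 to 1). Leukocytes or epithelial cells in the semen stay open: without S100A9, the leukocyte list had a median difference from the other 8 stallions of 0.30 (95% bootstrap interval over genes -0.02 to 0.51) in stallion 5 and -0.15 (-0.35 to -0.03) in stallion 6, and the epithelium list 0.18 (-0.03 to 0.42) and -0.0138 (-0.17 to 0.25), where the median difference over all probe sets was 0.18 and -0.03 on these arrays, so neither list was raised in both. A genotype shared by the pair and an effect of season within low-fertility stallions stay open, untested, with 2 animals. Other splits of the arrays do not decide about chance here, because those that keep this pair as a group of its own all gave at least the real count of 1: they were 5 of the 7 in 100 splits with as many probe sets for the interaction (highest other 249), 10 of the 13 in 100 for season (highest other 309) and 20 of the 21 in 60 for fertility (highest other 2).

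The late spermatid list was lower on the arrays of stallions 2, 9 and 10 than on the other arrays of their own groups, by means of -0.78, -1.14 and -1.31. With stallion 9 in spring, season and fertility class are the same for all arrays of a group and so are argued against as the whole cause. Each array lay at least 0.78 below the nearest of its own group (largest gap among the other arrays of a group 0.54). For stallion 2 that was a comparison with 1 array, and picking arrays for being low can enlarge such gaps. In autumn, where its title would place it, stallion 9 at 6.98 would share a group with stallion 2 at 6.85. The gaps of these 2 arrays to the nearest would then not hold, and the tests of this paragraph were not run that way. Scaling between the arrays, or loss of signal set by a gene's level alone, may account for stallion 2. Its gap was 0.34 after quantile normalization (largest other gap 0.42), and its list lay at the 5.74 percentile of 10000 random lists of similar level. The gaps of stallions 9 and 10 went from 1.08 and 1.04 to 0.70 and 0.75. Scaling is thus argued against as their whole cause but may be a part. Their lists lay at percentiles of 0.05 or less, which cannot decide about loss set by a gene's level. The random lists were matched only by broad ranges of level and drawn gene by gene. Members of the late spermatid list vary together (estimated correlation 0.55). Random lists also lay lower on these 2 arrays, by medians of -0.66 and -0.62. RNA quality, the share of immature or residual cytoplasm in the sample and a difference between stallions stay open, untested, and stallions 9 and 10 are also those whose array titles carry no running number.

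The arrays of stallions 2, 9 and 10 may be a source of the 4 list interactions, but leaving them out cannot decide it. They were picked for being low and lie in the 3 groups other than autumn with low fertility, so leaving them out tends to shrink a negative interaction. It also leaves stallion 1 alone in autumn with high fertility. Taking each list's mean per array, the flagellum, translation factor and ribosomal interactions went from -0.58 (SE 0.51), -0.53 (SE 0.60) and -0.44 (SE 0.62) to -0.20 (SE 0.27), -0.19 (SE 0.18) and -0.09 (SE 0.19). Each was less than 2 standard errors from 0 before and after. Without stallion 2 alone, translation factors were at -0.14 and ribosomal proteins at 0.03. The late spermatid list went from -0.82 (SE 0.84) to -0.38 (SE 0.42) without the 3 arrays, and the question stays open for it too. Chance is not excluded for these list counts: 26 of 100 splits gave as many as the real 4 for the interaction (highest other 12), 62 of 100 for season (real 1, highest other 13). For fertility the real count of 0 makes all 60 splits as large, which tests nothing (highest other 11). The split with 249 probe sets for the interaction placed stallions 2, 9 and 10 together in 1 group and that with 309 for season placed all 3 in autumn, which points to a structure of the arrays.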

How the results depend on the processing

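Settings that leave out the arrays of stallions 2, 9 and 10, use the array median as a covariate, keep single-symbol probe sets alone or add a term for the title format were chosen after seeing the data. The number of probe sets past the threshold was 1 for season, fertility and interaction and stayed 1 under quantile normalization, median centring, the filter, trend and robust eBayes, array weights, stallion 9 in autumn, the fold minimum, the covariate, single-symbol probe sets and the title term. It was 0 for season and 0 for fertility without the interaction term and with a single factor, 3 and 0 without moderation, and 0 for each of the 3 without stallions 2, 9 and 10, where 3 residual degrees of freedom remain. Leaving out each array gave 0 to 18 for season (0 without stallion 2 or 5, 2 without 1, 18 without 6), 0 to 13 for fertility (0 without 2, 4, 5 or 9, 13 without 6) and 0 to 15 for the interaction (0 without 2, 3, 4, 5, 9 or 10, 15 without 6). Where this left 1 array in a group, it was assumed to vary like the others. A count of 1 was not always LOC100061699: without stallion 1 it was GC for fertility and the interaction, and without moderation an unnamed probe set for the interaction. LOC100061699 itself ranged from -3.01 to -2.78 for season, 2.05 to 2.62 for fertility and -5.01 to -4.59 for the interaction.

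Gene lists past the threshold for season (1) became 0 with an estimated correlation, fry, quantile normalization or the filter, 7 with stallion 9 in autumn, 8 without stallions 2, 9 and 10, 5 with the covariate and 10 with the title term. For fertility (0) they became 1 without those 3 arrays and 1 with the title term. For the interaction (4) they became 0 with an estimated correlation or fry, 7 with stallion 9 in autumn and 1 without the 3 arrays. Leaving out each array gave 0 to 8 for season (0 without 2, 5 or 7, 2 without 3 or 8, 6 without 10, 7 without 6, 8 without 9), 0 to 2 for fertility (2 without 1, 3, 5 or 10) and 0 to 7 for the interaction (0 without 6 or 10, 1 without 2 or 4, 2 without 3, 7 without 5 or 9). Across arrays left out, the ribosomal list ranged from -0.16 to 0.31 for season, negative without stallion 2 or 3, and from -0.91 to 0.0276 for the interaction, positive without stallion 2. Apart from the smaller samples named, the cause was not tested. Of 162 values under alternatives of the 8 calls of LOC100061699 and gene lists, 101 kept their direction and stayed past the threshold, 58 fell short of it and 3 reversed. The other genes that the naming rule took outside the gene lists passed under none of the alternatives. Another pseudocount was not run, since the values are already logarithms. No paired analysis was possible because each array is a different stallion and the replicate numbers pair no animals. Values near the floor of 4 limit what can be seen of weak probe sets.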

Other observations

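The genes in these paragraphs were chosen after their values were seen, and the groupings described here were not tested. BSP1, which encodes a binder of sperm protein from the accessory glands, was at 8.40 in stallion 3 and 7.19 in stallion 4, both spring high-fertility, and at 4.30 to 4.86 in the other 8. CRISP3, a seminal plasma protein gene among the stallion fertility candidates, was at 7.52 in stallion 3 and at 4.25 to 5.17 in the others, and LCN2, a secreted lipocalin gene, at 8.22 in stallion 3 and 4.57 to 5.81 in the others. Stallion 3 had the highest value for 6 of the 25 measured genes of the epididymis and accessory gland list, as did stallion 5, and each of the other 8 stallions had it for 1 to 3.

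Besides LOC100061699 and GM2A, other probe sets stood at least 1 log2 unit higher in both autumn low-fertility stallions than in any other, 10 in all. S100A9, a calcium-binding protein gene of neutrophils and epithelia, was at 8.24 and 8.19 against 4.78 to 6.63, whereas its partner S100A8 was at 5.07 and at the floor of 4. CYP39A1 was at 7.17 and 7.46 against at most 5.64, PVRIG at 6.79 and 6.82 against at most 5.55, and LOC100061012 at 6.41 and 6.43 against at most 5.23. Of the 45 possible pairs of stallions, 4 had at least as many such probe sets, the real pair included. The pair of stallions 3 and 8, both in spring but of different fertility classes, had the most, 69.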
